A study of Mus musculus with 11 samples.

How the data were processed

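Gene expression was measured in mouse embryonic stem (ES) cells with Agilent one-colour arrays, 1 array for each of 11 samples. The cells had been kept for at least 3 passages in serum/LIF (3 arrays), 2i/LIF (5 arrays) or KOSR/LIF (3 arrays), per the labels. LIF is leukaemia inhibitory factor, 2i medium holds an inhibitor of MEK and an inhibitor of GSK3, and KOSR is a defined replacement for serum. Groups and replicate numbers were taken from the sample titles. The samples came from 3 ES cell lines. Titles and source names give different lines for replicates 1 to 4 of 2i/LIF, so the line was left out of the main test and each version was tried as an alternative.

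The authors extracted RNA with Qiagen RNeasy kits and labelled it with Cy3 by Agilent's one-colour protocol, per the labels' protocols. The deposited scanner values are intensities on a linear scale, background-subtracted and detrended within each array by Agilent Feature Extraction 11.0.1.1, per the file headers. They were not scaled between arrays. The deposited value table also holds intensities on a linear scale. Its columns share nearly the same quartiles and the same largest value, 194435, as quantile normalization gives, and the column medians ran from 46.5 to 47.7. How the authors made that table is not given in the sources used here.

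The scanner files name probes by accession and not by gene. Of 62976 spots, 59305 were not controls, and spots without an outlier flag were averaged to 55681 probes, of which 33 were left out because every spot carried such a flag on some array. Of 29123 probes with a RefSeq accession, 27656 were named through a RefSeq gene table of assembly GRCm38.p6, which gave 20972 genes. That table was used for names only, because the array's probe design used build mm9 per the file headers. Another 16194 probes for genomic regions, 2369 for Ensembl transcripts and 7995 others had no gene name here and stayed out of the gene tests.

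The log2 of each processed intensity was taken and the array's 75th percentile subtracted. A probe entered if it was well above background on at least 3 of the 11 arrays, which kept 21274 named probes. Of several probes of a gene, the one with the highest mean level over all arrays stood for the gene, so 16279 genes were tested. For 4162 of them more than 1 probe passed the filter, and probes of 1 gene were called in opposite directions in 2i/LIF against serum/LIF. One linear model over all 11 arrays (lmFit and eBayes of limma 3.58.1 in R 4.3.3, no covariates) gave the 3 comparisons between media, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit had 8 residual and 3.52 prior degrees of freedom, and the median SD between replicate arrays was 0.44 (log2). Where a probe was not well above background on any array of a medium, the fold is a bound, written "at least". It sets the brighter medium's mean against the mean, per array of the dimmer medium, of the higher of the dim probe's own signal and the lowest signal among probes well above background. For named genes that passed with the probe well above background on some but at most 50% of the dimmer medium's arrays, the same raising of dim signals gives a smaller log2 change, printed beside the fitted one, a step chosen after the data were seen. The number of arrays limits the precision. The labels call the samples replicate clones, and whether repeated 2i/LIF samples of a line came from separate cultures is not given in the sources used here, so p-values measure the spread between these samples.

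Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 36 lists that each had at least 5 measured members. The test was repeated with an estimated correlation and with fry. The lists (697 entries, 652 distinct genes, 610 of them tested) cover pluripotency, signalling targets, metabolism, cell cycle, stress responses and markers of other cell types. Lists, comparisons, tests, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule names 11 pluripotency and lineage genes in each comparison whatever their result. It adds up to 3 members of each list that passed (or of which at least 4 members and at least 1 in 3 passed) with the largest change in the majority direction, and 1 in the other direction. It also adds the 6 highest and 6 lowest genes whose arrays do not overlap between the media and whose symbol is not a clone or locus name.

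The gene test and camera at the preset correlation were tried on simulated data. Genes were drawn independently there, and 50 were given each size of change. Fewer genes changed there than were called in the data. Genes given a true log2 change of 2 were recovered in 88% of cases for 2i/LIF against serum/LIF, 64% for KOSR/LIF against serum/LIF and 80% for 2i/LIF against KOSR/LIF, with 16279 genes simulated in each. At a log2 change of 1 the shares were 14%, 12% and 10%. A shifted list was found in each of the 3 comparisons and 0 of the other lists were called in any. The correlation between genes of a list, estimated in the data, reached 0.62. With independent genes the simulation cannot show how camera treats such lists.

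Alternatives changed the background correction, the scaling, the filter on dim probes, the probe rule, the source of the values, blocks for cell line, replicate number, slide and scan day, array weights, and the arrays included. The planned background alternative (normexp, offset 50) was run on the median spot signal because the deposited scanner intensities used here hold no mean spot signal. The 11 arrays lie on 5 slides scanned on 3 days, and slide and scan day were used as blocks. Scan day 1 (slide 1) holds replicates 1 and 2 of serum/LIF, 3 and 4 of 2i/LIF, and 1 and 2 of KOSR/LIF. Scan day 2 holds replicate 2 of 2i/LIF and replicate 3 of KOSR/LIF, and scan day 3 holds replicate 3 of serum/LIF and replicates 1 and 5 of 2i/LIF.

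Each column of the deposited value table was set against every scanner array by rank correlation. The columns of replicates 1 and 4 of 2i/LIF followed each other's scanner array (rho 0.999 and 1.000) more closely than their own (0.967 for both), and the same held for replicates 1 and 2 of KOSR/LIF. The column of KOSR/LIF replicate 3 followed no scanner array closely: rho was 0.886 with its own and 0.977 with the nearest, KOSR/LIF replicate 1. These pairs lie within a medium, so the groups of the comparisons stayed as labelled.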

Results

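Expression in mouse ES cells was compared between 3 culture media that keep the cells self-renewing. Serum/LIF is the standard medium. 2i/LIF blocks MEK, the kinase above ERK, and GSK3, the kinase that marks beta-catenin for degradation. KOSR/LIF replaces serum with a defined supplement. The question, as the series title puts it in other words, is whether each medium holds the cells in a state of its own, resembling particular embryonic stages and cell types. There were 3 arrays of serum/LIF, 5 of 2i/LIF and 3 of KOSR/LIF, and 16279 genes were tested. Values below are log2 fold changes with their standard error (SE) unless a fold is named. The share of probes well above background ran from 53.7% to 72.6% on 10 arrays and was 43.7% on KOSR/LIF replicate 3. The 75th percentile of processed intensity was 65.3 on that array and 176 to 538 on the others.

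Each serum/LIF and 2i/LIF array correlated more closely with every array of its own medium than with any array of another medium, and KOSR/LIF replicates 1 and 2 did not. KOSR/LIF replicates 1 and 2 had r of 0.952 to 0.961 with the serum/LIF arrays and of 0.936 and 0.931 with KOSR/LIF replicate 3. Pearson's r between arrays of a medium, across genes, was 0.980 to 0.986 in serum/LIF, 0.949 to 0.981 in 2i/LIF and 0.931 to 0.984 in KOSR/LIF. The mean distance between media (1 minus r) was 2.15 times the mean distance within a medium, and 22 of 100000 permutations of the media gave a ratio as large (one-sided permutation p = 2e-04). The first principal component, with 40.3% of the variance, set the 5 arrays of 2i/LIF apart from the others. The second, with 19.5%, separated serum/LIF from KOSR/LIF, with KOSR/LIF replicate 3 far beyond the other KOSR/LIF arrays.

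**Figure D1:**
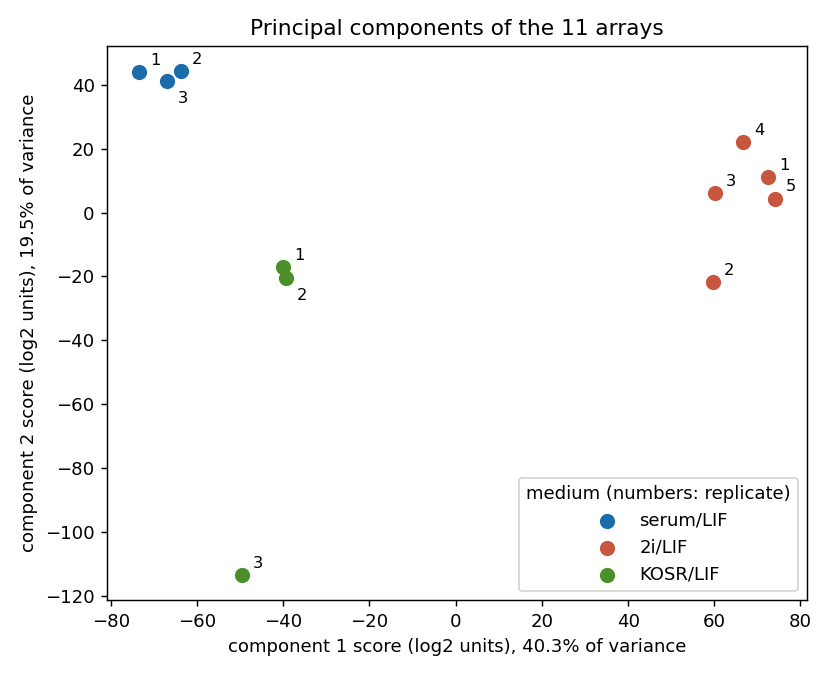
Scores of the 11 arrays on the first 2 principal components of 16279 genes (log2 units), coloured by medium and numbered by replicate. The 5 arrays of 2i/LIF lie at 59.6 or more on component 1 and the other 6 at -39.3 or less, and KOSR/LIF replicate 3 lies at -113 on component 2.

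Genes that ERK signalling switches on were lower in 2i/LIF than in serum/LIF. Of 22 measured ERK targets 15 fell (17 adjusted over the list alone), and the list's median was -2.13. Egr1, an immediate early transcription factor, fell by 7.76 ± 0.47 (adjusted p = 2.81e-06), or by 6.67 with the dim signals raised to the lowest signal well above background. The feedback regulators Dusp4, an ERK phosphatase (-5.51 ± 0.66), and Spry4 (at least 13.0-fold lower, adjusted p = 4.73e-06) also fell. Targets of serum response factor and YAP, which report on actin and growth factor input, fell in 15 of 24 members (17 over the list alone, median -1.86, adjusted p = 0.071 with an estimated correlation). Thbs1, a matrix glycoprotein, was at least 102-fold lower (adjusted p = 4.93e-06), and the contractile genes Cnn1 (-6.93 ± 0.59) and Acta1 (-5.29 ± 0.55) fell.

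Among the core pluripotency genes, Prdm14 rose and most others did not pass between these media. Log2 fold changes that did not pass were -0.07 ± 0.41 for Pou5f1, -0.55 ± 0.23 for Sox2, 0.82 ± 0.41 for Nanog, 0.41 ± 0.35 for Klf4, 0.09 ± 0.23 for Esrrb and -0.07 ± 0.48 for Dppa3. Prdm14, a regulator of the naive state that restrains DNA methylation, rose by 1.46 ± 0.26 (adjusted p = 0.00233), and the methyltransferase gene Dnmt3b fell by 1.88 ± 0.48 (adjusted p = 0.0179). The call on Dnmt3b was lost without serum/LIF replicate 1 (adjusted p = 0.088) or 2 (adjusted p = 0.068), and Nanog passed without KOSR/LIF replicate 3 (0.82, adjusted p = 0.016). In the naive pluripotency list 4 of 19 members rose and 1 fell (7 and 2 over the list alone, median 0.42, adjusted p = 0.28 with an estimated correlation). Spic rose by 4.45 ± 0.35 (21.9-fold) and Kit by 2.00 ± 0.29. In the general pluripotency list 4 of 18 fell (5 over the list alone, adjusted p = 0.49 with an estimated correlation), among them Lin28a (-3.01 ± 0.54) and Utf1 (-2.83 ± 0.46), genes that stay on as cells leave the naive state. The formative and primed epiblast list had 10 of 19 members lower (12 over the list alone, median -1.64, adjusted p = 0.071 with an estimated correlation). Fgf5, the classic marker of the post-implantation epiblast, was at least 36.2-fold lower (adjusted p = 0.000108), and Pou3f1 fell by 4.56 ± 0.32.

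Several lists of lineage markers held genes that fell in 2i/LIF against serum/LIF. Of 21 primitive endoderm genes 7 fell (8 fell and 1 rose over the list alone, adjusted p = 0.61 with an estimated correlation), including the endocytic genes Dab2 (-4.12 ± 0.83) and Lrp2 (-4.05 ± 0.47). Gata6 (-0.75 ± 0.98), Hhex (0.62 ± 0.43) and Cdx2 (-0.84 ± 1.07) did not pass. Of 21 trophoblast genes 7 fell and 2 rose (9 and 2 over the list alone, adjusted p = 0.27 with an estimated correlation). The epithelial keratin gene Krt18 fell by 5.13 ± 0.51, and the transcription factor gene Tfap2a rose by 2.88 ± 0.30. TGF-beta and Nodal targets fell in 5 of 12 (6 over the list alone, adjusted p = 0.086 with an estimated correlation), as did 4 of 12 blood and endothelial markers (5 over the list alone, adjusted p = 0.086 with an estimated correlation). Fibroblast markers fell in 6 of 15 members and rose in 1 (8 and 1 over the list alone, median -1.65, adjusted p = 0.19 with an estimated correlation), with Mmp2 at -3.42 ± 0.56. Of 16 neural genes 4 fell, and that list, definitive endoderm and mesoderm did not pass camera. The neural list did pass fry (adjusted p = 0.012). In the adhesion and matrix list 10 of 23 fell and 1 rose (12 and 1 over the list alone, adjusted p = 0.21 with an estimated correlation), and the collagen IV genes Col4a1 (-4.28 ± 0.69) and Col4a2 (-3.44 ± 0.45) were among them. Imprinted genes fell in 12 of 22 members and rose in 1 (15 and 1 over the list alone, median -1.41), with Peg10 at -5.02 ± 0.57, Dlk1 at -3.65 ± 0.71 and Plagl1 at 2.94 ± 0.50.

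Several lipid synthesis genes rose in 2i/LIF against serum/LIF. In the cholesterol biosynthesis list 10 of 26 rose and 1 fell (19 and 1 over the list alone, median 0.89, adjusted p = 0.19 with an estimated correlation). Insig1, which holds the sterol sensor in the endoplasmic reticulum, rose by 1.88 ± 0.27, and the pathway enzyme gene Msmo1 rose by 1.42 ± 0.22. Fatty acid synthesis genes rose in 6 of 16 (10 over the list alone, adjusted p = 0.20 with an estimated correlation), led by the desaturase gene Scd1 (2.83 ± 0.40). NRF2 targets rose in 3 of 15 (4 over the list alone, adjusted p = 0.61 with an estimated correlation), with the quinone reductase gene Nqo1 at 2.86 ± 0.27. Hox genes rose in 3 of 19 (3 over the list alone, median 1.41, adjusted p = 0.49 with an estimated correlation), with Hoxc4 at 5.54 ± 0.56. Large increases were found in Cnga4, a cyclic nucleotide-gated channel subunit (at least 45.2-fold, adjusted p = 4.24e-05), in Pglyrp1, a peptidoglycan recognition protein (6.26 ± 0.62), and in Dmgdh (6.32 ± 0.57) and Bhmt (6.17 ± 0.57), enzymes of choline and betaine breakdown. Fndc3c1 was at least 62.0-fold lower (adjusted p = 5.32e-07) and Kif1a fell by 7.41 ± 0.33. Of the genes named here, Egr1, Kif1a, Peg10 and Dab2 were well above background on 1 of 5 2i/LIF arrays, Cnn1 and Acta1 on 2 of 5, and Hoxc4 on 1 of 3 serum/LIF arrays. With those signals raised as for Egr1, the values were -6.77 for Kif1a, -4.17 for Peg10, -2.51 for Dab2, -6.60 for Cnn1, -5.03 for Acta1 and 5.21 for Hoxc4.

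In total, 2722 genes changed between 2i/LIF and serum/LIF, 1098 higher and 1624 lower in 2i/LIF, and 2407 of them by at least 2-fold. Camera passed 16 of 36 lists, 5 higher and 11 lower. The ERK target and imprinted gene lists also passed with an estimated correlation (adjusted p = 0.020 for both). With scan day as a block as well they did not (adjusted p = 0.055 and 0.086). Camera at the preset correlation did not pass germline genes (6 of 20 rose and 5 fell, adjusted p = 0.56) or Wnt and beta-catenin targets (5 of 17 rose and 1 fell, adjusted p = 0.11). Of the latter, Sp5 rose by 2.78 (adjusted p = 0.023) and Axin2 by 2.53 (adjusted p = 0.017). Both calls depended on single arrays: without serum/LIF replicate 2 the adjusted p was 0.12 for Sp5 and 0.084 for Axin2. LIF and STAT3 targets (1 of 14 rose and 5 fell, adjusted p = 0.15) and p53 targets (2 of 18 rose and 4 fell, adjusted p = 0.17) did not pass camera either. Fry passed 17 lists, among them LIF and STAT3 targets and p53 targets (adjusted p = 0.020 for each), neural genes (adjusted p = 0.012) and BMP targets (adjusted p = 0.0050). Primitive endoderm (adjusted p = 0.074), NRF2 targets (adjusted p = 0.080) and Hox genes (adjusted p = 0.051) did not pass fry. With scan day as a block 3386 genes changed, against 2379 within scan day 1 (2 arrays each) and 1117 within scan day 3 (2 arrays of 2i/LIF, 1 of serum/LIF). The 16 list medians kept their sign with the block and within both days, but calls were lost. Within scan day 1 these were general pluripotency, TGF-beta and Nodal targets and primitive endoderm (adjusted p = 0.061 for each), NRF2 targets (adjusted p = 0.11) and Hox genes (adjusted p = 0.22), and within scan day 3 general pluripotency (adjusted p = 0.11) and naive pluripotency (adjusted p = 0.073). The ERK targets stood at -2.12, -1.71 and -2.07, the serum response list at -1.95, -2.07 and -1.81, the imprinted genes at -1.35, -1.34 and -1.46, and cholesterol biosynthesis at 1.00, 0.92 and 0.85. The Hox median was 0.45 within scan day 1 against 2.03 within scan day 3, and that of primitive endoderm -0.66 against -1.65. Normexp background correction put the medians at -1.06 for ERK targets, -1.12 for the serum response list, -0.92 for imprinted genes, -0.63 for fibroblast markers, 0.71 for Hox genes and -0.32 for blood and endothelial markers, whose call was lost (adjusted p = 0.077). The primitive endoderm median was -0.32 with normexp, -0.07 without a filter on dim probes, -1.62 with a stricter one, -1.45 with slide as a block, -0.38 with replicate number as a block, -0.31 without 2i/LIF replicate 4, -1.19 without 2i/LIF replicate 2 and -1.40 without serum/LIF replicate 1. With replicate number as a block that of naive pluripotency was 0.25. The Hox median was 0.91 without 2i/LIF replicate 1 and 0.54 without replicates 1 and 5, and that of fibroblast markers -1.10 without serum/LIF replicate 3. The fit without 2i/LIF replicates 1 and 5 was planned as their deposited scanner data were smaller. It lost the call on NRF2 targets (camera adjusted p = 0.064). Without serum/LIF replicate 1, 657 genes were higher. Without serum/LIF replicate 3, the calls on primitive endoderm (median -0.28, adjusted p = 0.064), trophoblast (adjusted p = 0.054) and NRF2 targets (adjusted p = 0.077) were lost, and without serum/LIF replicate 2 that on general pluripotency (adjusted p = 0.053).

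**Figure D2:**
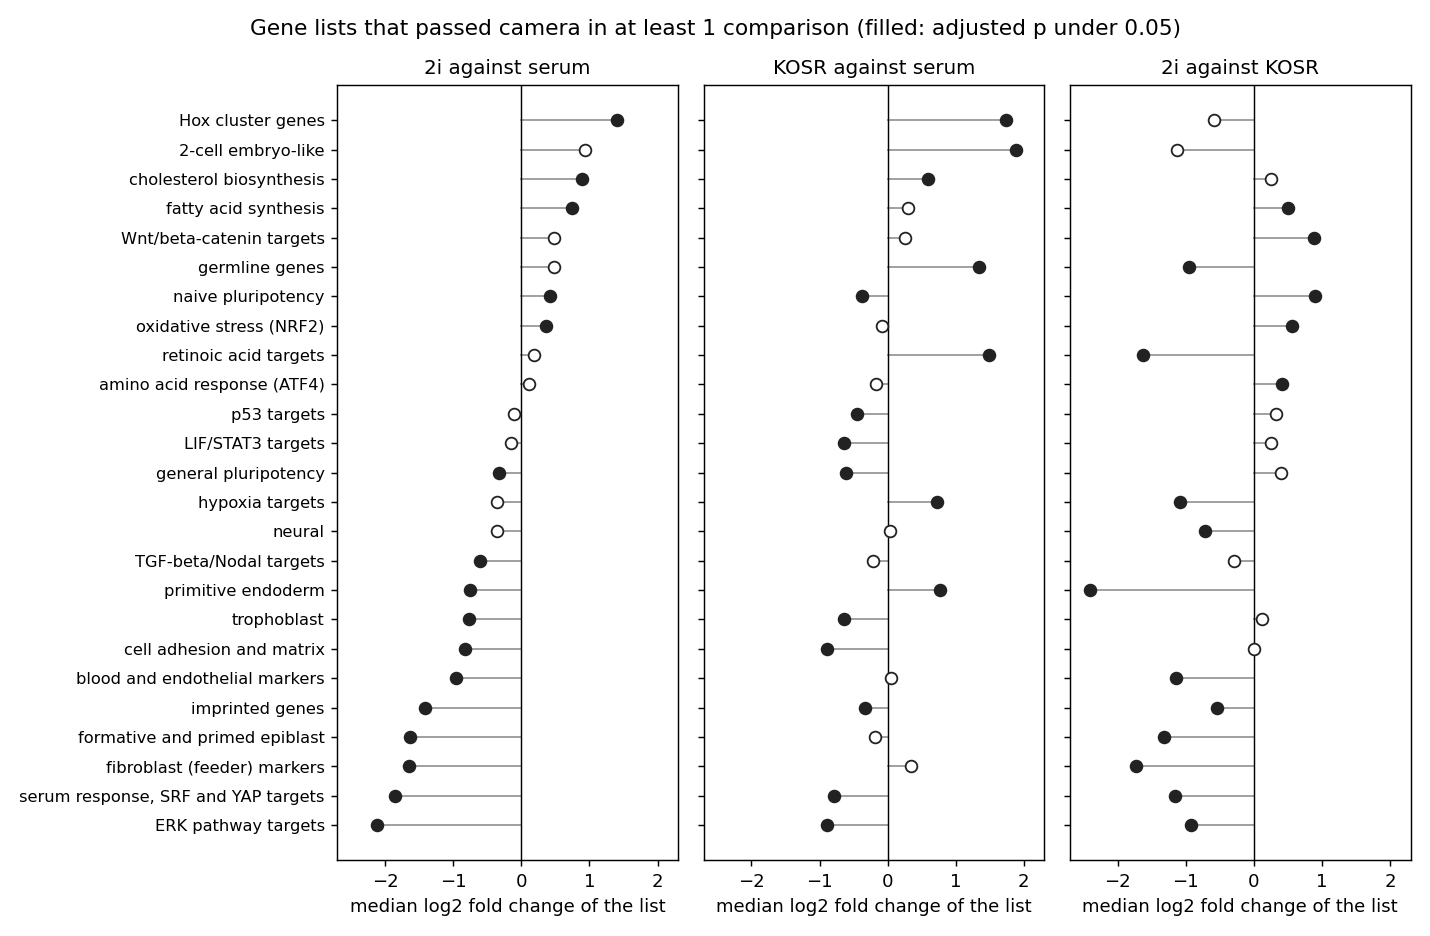
Median log2 fold change of each gene list that passed camera in at least 1 comparison, 1 panel per comparison, with filled points for lists at an adjusted p under 0.05 in that comparison. ERK targets have negative medians in all 3 panels. The trophoblast median for KOSR/LIF against serum/LIF is 0.02 under normexp background correction.

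Several germline and Hox genes rose in KOSR/LIF against serum/LIF. Of 20 germline genes 8 rose (13 adjusted over the list alone), with a median of 1.34 (adjusted p = 0.12 with an estimated correlation). Dazl, an RNA-binding protein of germ cells, rose by 3.58 ± 0.71 (adjusted p = 0.0169), Slc25a31, a nucleotide carrier of sperm, by 3.26 ± 0.37, and Asz1, a piRNA pathway gene, was at least 3.50-fold higher (adjusted p = 0.00818, well above background on 2 of 3 KOSR/LIF arrays). The call on Dazl was lost without serum/LIF replicate 1 (adjusted p = 0.078) or 2 (adjusted p = 0.067), or KOSR/LIF replicate 1 (adjusted p = 0.059) or 2 (adjusted p = 0.053). A higher level of Dazl than in serum/LIF was not particular to KOSR/LIF. Its log2 level was -2.85 to -1.40 on the serum/LIF arrays, -1.29 to 1.75 on 2i/LIF and 0.66 to 1.67 on KOSR/LIF. Of 19 Hox genes 9 rose (11 over the list alone), with a median of 1.74 (adjusted p = 0.21 with an estimated correlation). Hoxb2 rose by 4.42 ± 0.60. Slc25a31 and Hoxb2 were well above background on 1 of 3 serum/LIF arrays, and with the dim signals raised they stood at 3.10 and 3.82.

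Retinoic acid targets rose in 3 of 13 members (7 rose and 1 fell over the list alone, median 1.49, adjusted p = 0.21 with an estimated correlation). Stra8, which starts meiosis, rose by 6.09 ± 1.19, the retinol transporter gene Stra6 by 3.77 ± 0.55 (3.08 with the dim signals raised) and the retinal reductase gene Dhrs3 by 1.97 ± 0.30. The log2 level of Stra8 was 3.19 on serum/LIF replicate 3 against -1.35 and -0.46 on replicates 1 and 2, and without replicate 3 its change was 7.46. Its call was lost without serum/LIF replicate 1 (5.19, adjusted p = 0.075) or 2 (5.63, adjusted p = 0.064), or KOSR/LIF replicate 1 (5.86, adjusted p = 0.053) or 2 (5.99, adjusted p = 0.051). Primitive endoderm genes rose in 2 of 21 (9 over the list alone, median 0.77, adjusted p = 0.46 with an estimated correlation), with the endoderm transcription factor gene Gata4 at 2.16 ± 0.38 (2.02 and adjusted p = 0.053 without serum/LIF replicate 1). Gata6 stood at 3.49 and did not pass (adjusted p = 0.103), except without KOSR/LIF replicate 3 (4.79, adjusted p = 0.022). In the list of 2-cell embryo genes 1 of 15 rose and 1 fell (6 and 2 over the list alone, median 1.89, adjusted p = 0.26 with an estimated correlation). Cholesterol genes rose in 2 of 26 (4 over the list alone, adjusted p = 0.21 with an estimated correlation). Hypoxia targets rose in 2 of 15 (2 over the list alone, adjusted p = 0.48 with an estimated correlation).

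Several pluripotency and adhesion genes fell in KOSR/LIF against serum/LIF. Naive pluripotency genes fell in 5 of 19 (8 over the list alone, median -0.37, adjusted p = 0.21 with an estimated correlation). Dppa3, a maternal factor of naive cells and germ cells, fell by 2.84 ± 0.54 (adjusted p = 0.0145), but its call was lost without serum/LIF replicate 2 (adjusted p = 0.053) or 3 (adjusted p = 0.058). General pluripotency genes fell in 2 of 18 (4 over the list alone, adjusted p = 0.21 with an estimated correlation). Sox2 was among them at -1.35 ± 0.25 (adjusted p = 0.0132), and its call was lost without serum/LIF replicate 1 (adjusted p = 0.053) or 3 (adjusted p = 0.054). Pou5f1 (-1.09 ± 0.46), Nanog (-0.99 ± 0.46), Klf4 (-0.02 ± 0.39), Esrrb (-0.81 ± 0.26), Prdm14 (-0.24 ± 0.29), Dnmt3b (-1.21 ± 0.54), Hhex (0.22 ± 0.48) and Cdx2 (-2.19 ± 1.19) did not pass. Pou5f1 and Nanog levels were lowest on KOSR/LIF replicate 3 (3.69 and 1.21), and without it the changes were -0.39 and -0.33. Adhesion and matrix genes fell in 6 of 23 (11 fell and 1 rose over the list alone, median -0.89, adjusted p = 0.21 with an estimated correlation), with the tight junction claudin gene Cldn7 at -2.96 ± 0.43. The sorting adaptor gene Ap1m2 fell by 4.31 ± 0.75. Of 21 trophoblast genes 2 fell (3 over the list alone, adjusted p = 0.24 with an estimated correlation), with the keratin gene Krt18 at -3.23 ± 0.57 (-2.92 and adjusted p = 0.054 without serum/LIF replicate 1). Cfc1, a co-receptor for Nodal, was at least 23.0-fold lower (adjusted p = 0.00438), and at least 37.5-fold without KOSR/LIF replicate 3.

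Some targets of several signalling pathways fell in KOSR/LIF against serum/LIF. ERK targets fell in 3 of 22 (10 over the list alone, median -0.88, adjusted p = 0.12 with an estimated correlation). Serum response targets fell in 3 of 24 (9 fell and 1 rose over the list alone, median -0.79, adjusted p = 0.21 with an estimated correlation), with Thbs1 at -3.92 ± 0.65. LIF and STAT3 targets fell in 3 of 14 (4 over the list alone, median -0.64, adjusted p = 0.21 with an estimated correlation), including Tfcp2l1 (-1.42 ± 0.28), whose call was lost without serum/LIF replicate 2 (adjusted p = 0.053) or 3 (adjusted p = 0.065). Among p53 targets 2 of 18 fell and 1 rose (4 and 1 over the list alone, adjusted p = 0.21 with an estimated correlation). Of 22 imprinted genes 1 fell, Magel2 at -2.35 ± 0.30 (3 over the list alone, adjusted p = 0.21 with an estimated correlation).

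In total, 745 genes changed between KOSR/LIF and serum/LIF, 386 higher and 359 lower in KOSR/LIF. Camera passed 16 of 36 lists, 7 higher and 9 lower. With an estimated correlation camera passed 0 lists (6 at an unadjusted p under 0.05). Fry passed 15, not all of them among the 16. It did not pass primitive endoderm (adjusted p = 0.16), 2-cell embryo genes (adjusted p = 0.075) or hypoxia targets (adjusted p = 0.18). It did pass BMP targets (adjusted p = 0.020) and TGF-beta and Nodal targets (adjusted p = 0.027). With scan day as a block 999 genes changed, and 685 within scan day 1 (2 arrays each). Germline genes had medians of 1.51 with the block and 1.56 within scan day 1, Hox genes 2.24 and 1.86, retinoic acid targets 1.57 and 1.53, primitive endoderm 1.16 and 1.49, and ERK targets -0.79 and -0.90. The 16 medians kept their sign in both, though that of LIF and STAT3 targets was -0.16 and that of trophoblast genes -0.19 within scan day 1. The calls on naive pluripotency (adjusted p = 0.069), trophoblast (adjusted p = 0.18) and imprinted genes (adjusted p = 0.063) were lost there. The count was sensitive to single arrays. It was 225 without serum/LIF replicate 1, 331 without replicate 2 and 391 without replicate 3, 395 and 386 without KOSR/LIF replicates 1 and 2, and 631 without KOSR/LIF replicate 3, the faint array. Of 49 called genes examined one by one, 14 kept their call whichever array was left out, among them Asz1, Slc25a31, Hoxb2, Stra6, Dhrs3, Cldn7, Ap1m2, Cfc1, Thbs1 and Magel2. Without KOSR/LIF replicate 1, the calls on primitive endoderm (median 0.02, adjusted p = 0.076), trophoblast (adjusted p = 0.051), hypoxia (adjusted p = 0.068) and imprinted genes (adjusted p = 0.055) were lost. Without serum/LIF replicate 3, trophoblast was also lost (adjusted p = 0.068), and under normexp background correction its median was 0.02. Normexp put the medians at 0.78 for Hox genes, 0.85 for retinoic acid targets, 0.83 for 2-cell embryo genes and -0.57 for ERK targets, and a stricter filter on dim probes put that of Hox genes at 2.67. Median scaling put them at 0.39 for primitive endoderm, -0.75 for naive pluripotency and -1.01 for LIF and STAT3 targets, and quantile normalization put primitive endoderm at 0.42. Naive pluripotency stood at -0.21 with scan day and -0.17 with slide as a block, and LIF and STAT3 targets at -0.35 and -0.16. Primitive endoderm stood at 1.51 with slide as a block. Array weights gave 1.84 for primitive endoderm and -0.20 for LIF and STAT3 targets, and without KOSR/LIF replicate 3 the medians were 1.36 and -0.21. The deposited value table gave -0.54 for ERK targets, -0.55 for adhesion and matrix genes and -0.31 for LIF and STAT3 targets. With it the calls on p53 targets (adjusted p = 0.10) and imprinted genes (adjusted p = 0.20) were lost. The share of changed genes that were higher was 51.8%, against 24.6% with median scaling, 41.1% with quantile normalization and 38.0% with normexp, and median scaling moved the median of all genes by -0.37.

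Genes of the primitive endoderm, the extra-embryonic lineage that forms beside the epiblast, were mostly lower in 2i/LIF than in KOSR/LIF. Of 21 measured members 14 were lower in 2i/LIF (15 adjusted over the list alone), with a median of -2.41 (adjusted p = 0.26 with an estimated correlation). Gata6, its master regulator, fell by 4.24 ± 0.98 (adjusted p = 0.0127, and well above background on 2 of 3 KOSR/LIF arrays), and Dab2 (-4.89 ± 0.83), Col4a1 (-4.71 ± 0.69) and the endocytic receptor gene Cubn (-4.56 ± 0.74) also fell. The call on Gata6 was lost without KOSR/LIF replicate 1 (-3.41, adjusted p = 0.062) or 2 (-3.77, adjusted p = 0.056), and without replicate 3 its change was -5.54. With dim signals raised, Dab2 stood at -3.27 and Cubn at -4.25. Of the fibroblast markers 7 of 15 fell and 1 rose (9 and 1 over the list alone, median -1.73, adjusted p = 0.15 with an estimated correlation), with Col1a2 at -4.38 ± 0.39. In the naive pluripotency list 11 of 19 members rose in 2i/LIF (12 over the list alone, median 0.90, adjusted p = 0.12 with an estimated correlation). Spic rose by 4.83 ± 0.35 (28.4-fold), Tfcp2l1 by 2.88 ± 0.25 and Dppa3 by 2.77 ± 0.48.

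Several pluripotency genes were higher in 2i/LIF than in KOSR/LIF. Nanog rose by 1.81 ± 0.41 (adjusted p = 0.0113), but a dimmer probe of Nanog stood at -2.22 (adjusted p = 0.53), and the mean of both at -0.21. Without KOSR/LIF replicate 3 Nanog stood at 1.15. Prdm14 rose by 1.70 ± 0.26, Esrrb by 0.90 ± 0.23 and Sox2 by 0.80 ± 0.23. The call on Esrrb was lost without 2i/LIF replicate 4 (0.85, adjusted p = 0.052) or KOSR/LIF replicate 1 (0.93, adjusted p = 0.059) or 3 (0.80, adjusted p = 0.064). The value of Sox2 ran from 0.18 to 1.09 over 31 settings, and its call was lost in 18 of them. Among these were the fits without serum/LIF replicate 1 (adjusted p = 0.053), without 2i/LIF replicate 1 (adjusted p = 0.064), 3 (adjusted p = 0.062), 4 (adjusted p = 0.074) or 5 (adjusted p = 0.054), and without KOSR/LIF replicate 2 (adjusted p = 0.057) or 3 (0.58, adjusted p = 0.099). Log2 fold changes of Pou5f1 (1.02 ± 0.41), Klf4 (0.43 ± 0.35), Dnmt3b (-0.68 ± 0.48), Hhex (0.40 ± 0.43) and Cdx2 (1.35 ± 1.07) did not pass, and Pou5f1 stood at 0.32 without KOSR/LIF replicate 3. The formative and primed epiblast list had 11 of 19 members lower and 1 higher (12 and 2 over the list alone, median -1.32, adjusted p = 0.12 with an estimated correlation), with Fgf5 at least 5.99-fold lower (adjusted p = 0.00318, and at least 3.16-fold without KOSR/LIF replicate 3) and Sox4 at -3.17 ± 0.42. Of 16 neural genes 4 fell (6 over the list alone, adjusted p = 0.46 with an estimated correlation), including Sox11 (-3.93 ± 0.46) and Pax6 (-3.50 ± 0.42). Blood and endothelial markers fell in 5 of 12 (6 fell and 1 rose over the list alone, adjusted p = 0.12 with an estimated correlation), with Esam at -3.43 ± 0.53.

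Germline genes fell in 10 of 20 members and rose in 1 (11 and 1 over the list alone, median -0.95, adjusted p = 0.12 with an estimated correlation). The piRNA pathway genes Mael (-4.07 ± 0.32) and Piwil2 (-3.07 ± 0.27) fell and Rpl10l (1.49 ± 0.26) rose. Retinoic acid targets fell in 8 of 13 and rose in 1 (10 and 2 over the list alone, median -1.63, adjusted p = 0.24 with an estimated correlation), with Cyp26a1, which degrades retinoic acid, at -3.47 ± 0.30. ERK targets fell in 10 of 22 and rose in 1 (10 and 1 over the list alone, median -0.93, adjusted p = 0.12 with an estimated correlation), and Egr1 fell by 5.78 ± 0.47. Serum response targets fell in 10 of 24 (12 fell and 1 rose over the list alone, adjusted p = 0.24 with an estimated correlation), including the contractile genes Cnn1 (-5.31 ± 0.59), Acta2 (-5.11 ± 0.78) and Myl9 (-4.66 ± 0.37). Hypoxia targets fell in 8 of 15 (9 fell and 1 rose over the list alone, median -1.08, adjusted p = 0.30 with an estimated correlation), and Adm fell by 2.62 ± 0.57. Imprinted genes fell in 8 of 22 and rose in 1 (9 and 1 over the list alone, adjusted p = 0.12 with an estimated correlation).

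Metabolic and Wnt target genes were among those higher in 2i/LIF than in KOSR/LIF. ATF4 targets of the amino acid response rose in 6 of 25 (6 over the list alone, median 0.41, adjusted p = 0.58 with an estimated correlation), with the cystathionase gene Cth at 2.12 ± 0.35 and asparagine synthetase, Asns, at 1.45 ± 0.19. Fatty acid synthesis genes rose in 3 of 16 (6 over the list alone, adjusted p = 0.46 with an estimated correlation) and NRF2 targets in 3 of 15 (4 over the list alone, adjusted p = 0.67 with an estimated correlation), with Scd1 at 2.23 ± 0.40 and Gstm1 at 1.86 ± 0.30. Wnt and beta-catenin targets rose in 4 of 17 and fell in 2 (6 and 2 over the list alone, median 0.89, adjusted p = 0.62 with an estimated correlation). Sp5, a direct Wnt target, rose by 6.87 ± 0.75 (117-fold) and Axin2 by 3.45 ± 0.64, while Wnt8a fell by 2.93 ± 0.60. Against serum/LIF the rises in 2i/LIF were 2.78 for Sp5 and 2.53 for Axin2. The remainder of each difference is a mean level in KOSR/LIF below that in serum/LIF. Of the genes named here, Egr1, Cyp26a1, Pax6 and Wnt8a were well above background on 1 of 5 2i/LIF arrays, Cnn1, Sox11 and Esam on 2 of 5, and Axin2 on 1 of 3 KOSR/LIF arrays. With the dim signals raised they stood at -4.69, -3.15, -2.48, -1.94, -4.98, -3.61, -2.51 and 2.84.

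In total, 2388 genes changed between 2i/LIF and KOSR/LIF, 969 higher and 1419 lower in 2i/LIF. The share that was higher was 40.6%, against 52.3% with median scaling, which moved the median of all genes by 0.29. Camera passed 16 of 36 lists, 5 higher and 11 lower. With an estimated correlation it passed 0 (7 at an unadjusted p under 0.05). Fry passed 14, not all of them among the 16. Wnt targets (adjusted p = 0.088), ATF4 targets (adjusted p = 0.062) and NRF2 targets (adjusted p = 0.093) did not pass fry. TGF-beta and Nodal targets did (adjusted p = 0.00042). With scan day as a block 2809 genes changed, and 2071 within scan day 1 (2 arrays each). Scan day 2 held 1 array of each medium, and of the genes called within scan day 1, 87.7% had the same sign there. The medians with the block, within scan day 1 and within scan day 2 were -2.38, -2.89 and -1.23 for primitive endoderm, -1.93, -2.25 and -1.24 for fibroblast markers, 0.93, 0.82 and 1.12 for naive pluripotency, -1.11, -1.12 and -1.07 for germline genes, and -2.02, -1.39 and -2.48 for retinoic acid targets. The Wnt target list changed sign within scan day 2 (-0.33) and lost its call with the block (0.69, adjusted p = 0.18), as did NRF2 targets (0.67, adjusted p = 0.051). Within scan day 1 the calls on Wnt targets (adjusted p = 0.070), neural genes (adjusted p = 0.16), fatty acid synthesis (adjusted p = 0.081) and NRF2 targets (adjusted p = 0.54) were lost. Without KOSR/LIF replicate 3, the faint array, 1958 genes changed, the primitive endoderm median was -2.90, and the calls on neural genes (adjusted p = 0.23) and NRF2 targets (adjusted p = 0.22) were lost. The ATF4 target median was 0.69 with median scaling, 0.62 with normexp, 0.27 with slide as a block and 1.11 within scan day 2. Normexp put the medians at -1.38 for primitive endoderm, -0.74 for fibroblast markers, -0.97 for retinoic acid targets and 0.39 for Wnt targets, whose call was lost (adjusted p = 0.090). The Wnt list also lost its call without KOSR/LIF replicate 1 (adjusted p = 0.082) or 2 (adjusted p = 0.13), or 2i/LIF replicate 1 (adjusted p = 0.087). Without both 2i/LIF replicates 1 and 5, the calls on Wnt targets (camera adjusted p = 0.15) and NRF2 targets (camera adjusted p = 0.10) were lost.

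**Figure D3:**
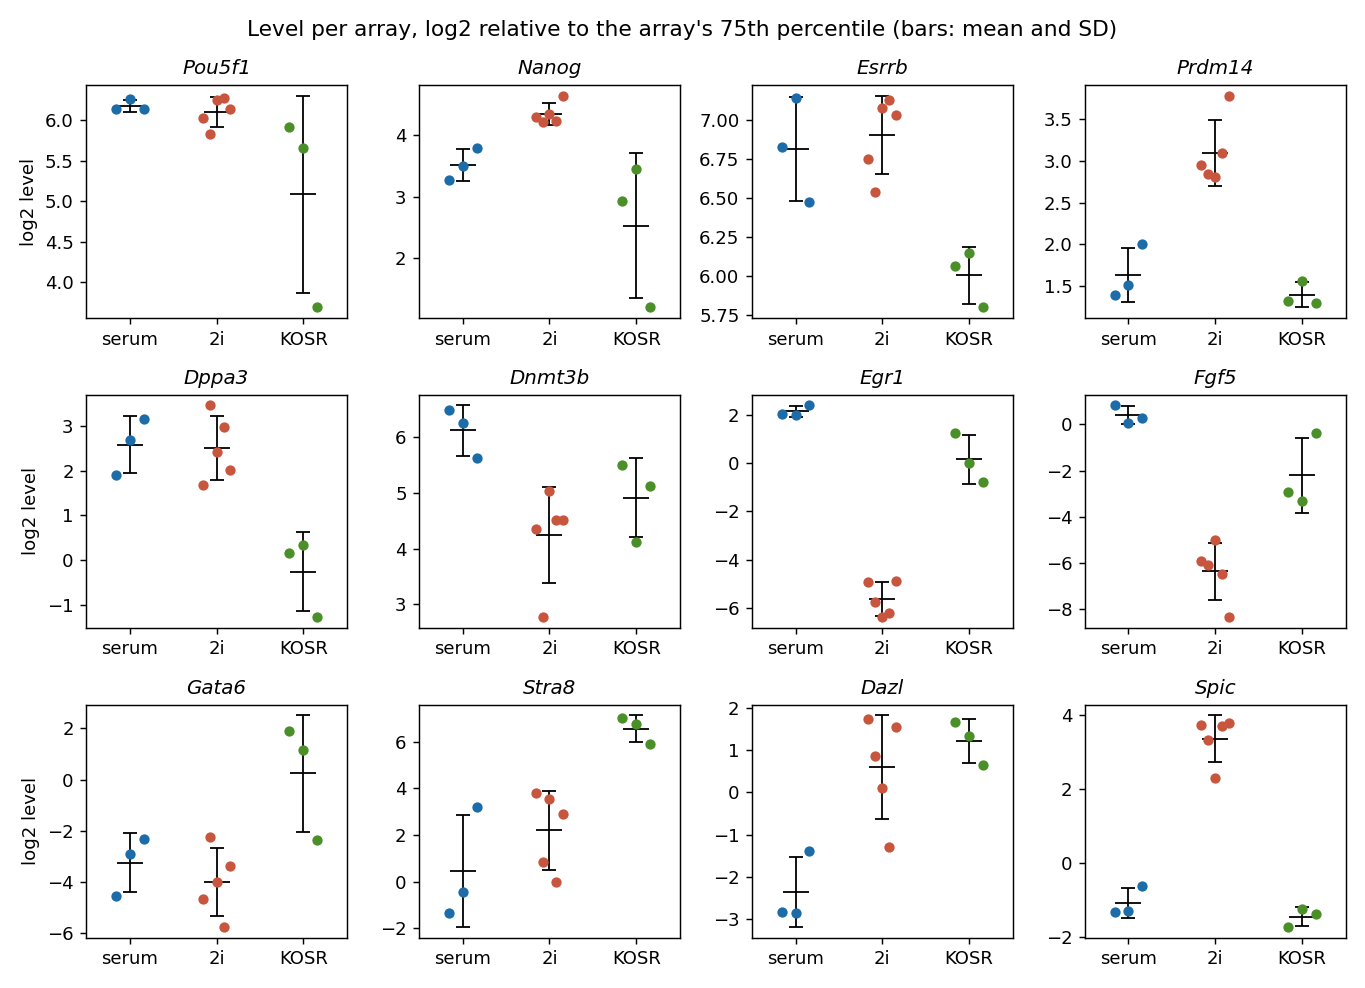
Level of 12 genes on each array, as log2 relative to the array's 75th percentile, with the mean and SD of each medium (serum/LIF 3 arrays, 2i/LIF 5, KOSR/LIF 3). Egr1 averages 2.14 in serum/LIF, 0.15 in KOSR/LIF and -5.63 in 2i/LIF, and Stra8 averages 0.46, 6.55 and 2.21, with serum/LIF replicate 3 at 3.19.

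Changes in 2i/LIF and in KOSR/LIF against the same serum/LIF arrays were compared across genes. There were 193 genes higher in both media and 222 lower in both, where independent lists would share 26.0 and 35.8, and 27 genes were called in opposite directions, where independent lists would share 62.7. Thbs1, Cfc1 and Magel2 were lower in both. Pearson's r between the fold changes was 0.51, against a median of 0.56 in 100 simulations of unchanged groups against these controls. Without true changes r depends on the numbers of arrays alone, so the lower r does not mean less sharing than noise gives. The covariance was 0.476 against 0.0988 in the simulations, a difference of 0.377. Genes are not independent replicates. The 3 serum/LIF arrays were not split between the comparisons, since a comparison would be left with a single array. In each of the 100 simulations 0 genes were called in both media, in the same or in opposite directions. No gene truly changed there, so the part of the overlap that the shared controls give was not measured.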

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

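The tests on near-identical gene copies were chosen after the result was seen. The 5 arrays of 2i/LIF were tested for 179 measures, the named genes and a pair of signal measures, and 10 had an array whose gap to its nearest neighbour took an unusually large share of the range, where chance gives about 1 in 20 groups, or 8.95. On 2i/LIF replicate 2 that share was 0.758 for Hand1, 0.782 for Id1, 0.731 for Id3, 0.777 for Myc, 0.898 for Piwil2 and 0.755 for Acta2. It was 0.777 for Ggps1 on replicate 1, 0.713 for Thrsp and 0.824 for Ccnd2 on replicate 4, and 0.730 for Perp on replicate 5. Id1 stood at -4.08 on 2i/LIF replicate 2 against a median of -1.66 on the other 2i/LIF arrays, and Acta2 at 0.05 against -3.08. Probes for genomic regions without a gene name took no part in the gene tests, and 205 of them changed between 2i/LIF and serum/LIF (95 higher, 110 lower), 13 between KOSR/LIF and serum/LIF (10 higher, 3 lower) and 108 between 2i/LIF and KOSR/LIF (29 higher, 79 lower).

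Whether chance could group the arrays this way was tested by refitting other splits of the same sizes. Of 56 splits for 2i/LIF against serum/LIF, 1, the real one, gave as many as 2722 genes, and the highest other gave 16. Of 56 splits for 2i/LIF against KOSR/LIF, 1, the real one, gave as many as 2388, and the highest other gave 55. For KOSR/LIF against serum/LIF the 10 splits are too few for a share under 0.05. The real split gave 745 genes and the highest other gave 0.

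The array of KOSR/LIF replicate 3 stood apart from the other KOSR/LIF arrays. The values argue against low signal as the whole cause: among the brightest genes the SD of its difference from the other arrays was 2.32 times the SD between those, against 1.60 among the dimmest. RNA of another medium stays open: on this array 75.3% of genes called between KOSR/LIF and serum/LIF without it, and 79.8% of those called between 2i/LIF and KOSR/LIF, lay nearer the KOSR/LIF mean. Scan day also stays open, since 2i/LIF replicate 2 of the same day had a ratio of 1.72. Scanner values from another hybridization than the value table's column stay open and were not tested further: that column followed the array at rho 0.886 and KOSR/LIF replicate 1 at 0.977, and no biological explanation was tested.

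Of 20 germline genes 8 were higher in KOSR/LIF than in serum/LIF (adjusted p = 0.12 for the list with an estimated correlation). So were 22 of 42 members of families with many near-identical copies. These included 4 of 7 in Xlr, 4 of 7 in Magea and 6 of 17 in Rhox. The family rise was not particular to KOSR/LIF: in 2i/LIF against serum/LIF 25 of the 42 rose and 3 fell. There 6 of 7 rose in Xlr, 6 of 7 in Magea and 6 of 17 in Rhox, where 2 fell. In 2i/LIF against KOSR/LIF 3 of the 42 rose and 5 fell. In the germline list 8 members rose that have no lettered copy or pseudogene of the same name in the annotation. Copies were sought by name and no sequences were compared, so this count cannot exclude signal shared between similar genes. For the families the question stays open too. The median SD of fold changes among members was 1.69, against 0.25 between probes of single genes, but members may still share signal. The medium, which the design names, stays among the open explanations.

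Of 21 primitive endoderm genes 14 were higher in KOSR/LIF than in 2i/LIF (adjusted p = 0.26 for the list with an estimated correlation). A single KOSR/LIF array does not account for the whole shift against 2i/LIF, since the median nearest 0 with an array left out was -1.74 (without KOSR/LIF replicate 1), against -2.41 with all. Against serum/LIF the rise in KOSR/LIF did rest on that array: the median of 0.77 was 0.02 without it (camera adjusted p = 0.076). Lower levels in 2i/LIF were part of the shift, as 7 of the 21 genes fell in 2i/LIF against serum/LIF. Fibroblasts in the KOSR/LIF cultures may contribute and cannot be told apart: Col1a1, Col1a2 and Col3a1 stood at 3.27, 4.38 and 2.14 over 2i/LIF (adjusted p = 0.0154, 4.76e-05 and 0.102) and had a median of 0.49 over serum/LIF, where the fibroblast list did not pass (1 of 15 rose, median 0.35, adjusted p = 0.80, and -0.08 with scan day as a block). Col1a2 passed over serum/LIF (1.97, adjusted p = 0.0271), but not without serum/LIF replicate 1 (adjusted p = 0.107) or 2 (adjusted p = 0.101) or KOSR/LIF replicate 1 (adjusted p = 0.065) or 2 (adjusted p = 0.096), and Col1a1 over 2i/LIF not without KOSR/LIF replicate 1 (adjusted p = 0.055) or 2 (adjusted p = 0.054), while Col3a1 passed there without 2i/LIF replicate 2 (adjusted p = 0.00247). Cells of the primitive endoderm lineage, or a change of state in the ES cells, were not tested apart.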

How the results depend on the processing

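The settings restricted to a scan day, without the arrays of scan day 2, and with scan day and an estimated correlation together were chosen after the data were seen. Where no cause is named below, the cause was not tested. Normexp gave 1753 genes for 2i/LIF against serum/LIF (707 higher, 1046 lower), 371 for KOSR/LIF against serum/LIF (141 and 230) and 1512 for 2i/LIF against KOSR/LIF (823 lower). It put r between the changes at 0.46 and Egr2 in KOSR/LIF against serum/LIF at 0.12, the other direction. Quantile normalization gave 250 higher genes in KOSR/LIF against serum/LIF and r of 0.49. Median scaling gave 691 higher in 2i/LIF and 141 higher in KOSR/LIF against serum/LIF, and 831 lower in 2i/LIF against KOSR/LIF. Without the filter on dim probes KOSR/LIF against serum/LIF gave 451 (244 higher, 207 lower), with more genes tested. With the mean of a gene's probes, Nanog in 2i/LIF against KOSR/LIF stood at -0.21, the other direction, because its probes differ. Array weights gave 4250 (1965 higher), 3194 (1696 higher, 1498 lower) and 4134 (1770 higher, 2364 lower). Averaging 2i/LIF arrays of a line gave 1168 for KOSR/LIF against serum/LIF (612 higher, 556 lower) with lines as in the titles and 557 lower with lines as in the source names.

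Replicate number as a block, with fewer arrays, gave 720 higher in 2i/LIF against serum/LIF, 238 lower in KOSR/LIF against serum/LIF, and 1408 in 2i/LIF against KOSR/LIF (489 higher, 919 lower). No pairing by replicate number was seen: residuals of arrays sharing a number correlated at a mean of 0.00997 (range -0.20 to 0.18). For arrays of different media sharing a scan day the mean was 0.089, against -0.054 for other pairs. For slide it was 0.070 against -0.033. For cell line it was 0.045 against -0.021 as in the titles, and 0.058 against -0.027 as in the source names. Pairing by number or line cannot be excluded. Value table columns of 2i/LIF replicates 1 and 4, and of KOSR/LIF replicates 1 and 2, followed each other's arrays. That of KOSR/LIF replicate 3 followed none closely, so which number and line these arrays carry is uncertain. Slide as a block gave 1704 higher in 2i/LIF against serum/LIF and r of 0.46. Scan day 1 alone gave r of 0.47 and a separation of 3.39 (permutation p = 0.0671, with 6 arrays). With so few arrays the distinct groupings are too few for a permutation p under 0.05. Scan day 3 alone gave 1117 for 2i/LIF against serum/LIF (400 higher, 717 lower), with 3 arrays. Camera with an estimated correlation passed 2, 0 and 0 lists (9, 6 and 7 at an unadjusted p under 0.05), with scan day as a block as well 0, 0 and 0 (9, 8 and 7), and fry passed 17, 15 and 14. Of the 48 list calls that camera made at the preset correlation, fry kept 39 and lost 9.

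With each array left out in turn, 2i/LIF against serum/LIF gave 1869 to 3203 genes (657 to 1407 higher, 1212 to 1796 lower), KOSR/LIF against serum/LIF 225 to 915 (123 to 470 higher, 102 to 445 lower) and 2i/LIF against KOSR/LIF 1759 to 2593 (684 to 1077 higher, 1060 to 1516 lower). The lists passed numbered 13 to 18, 12 to 20 and 14 to 18, r ran from 0.47 to 0.54 and the separation from 2.01 to 2.36. KOSR/LIF against serum/LIF gave 225, 331 and 391 without serum/LIF replicates 1, 2 and 3, and 395 and 386 without KOSR/LIF replicates 1 and 2. Higher genes in 2i/LIF against serum/LIF numbered 657 without serum/LIF replicate 1. Of the called genes examined one by one, 75 of 92, 14 of 49 and 76 of 94 kept their call without each array. Signal over background limits the dim genes, most on KOSR/LIF replicate 3, where 43.7% of probes stood well above it.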

Other observations

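The interferon and choline lists were chosen after the genes with the largest changes were seen. Of 28 interferon-inducible and antigen presentation genes 15 fell in 2i/LIF against serum/LIF and 2 rose, with a median of -1.01 (camera adjusted p = 1.11e-05, and adjusted p = 0.052 with an estimated correlation). The guanylate-binding protein genes Gbp2b (-6.92 ± 0.40) and Gbp2 (-6.68 ± 0.47), the immunoproteasome gene Psmb8 (-5.80 ± 0.45), the peptide transporter gene Tap2 (-3.91 ± 0.40) and B2m, the light chain of MHC class I (-1.53 ± 0.43), fell, and Oas1a rose (3.12 ± 0.50). Without the members among the 25 largest changes each way the median was -0.90 (camera adjusted p = 0.00679, and adjusted p = 0.052 with an estimated correlation). So the shift was not confined to those members. The others were also chosen after the data were seen, so the choice of genes cannot be excluded as a cause. In KOSR/LIF against serum/LIF 6 of 28 fell (median -0.66, adjusted p = 3.05e-05, and adjusted p = 0.090 with an estimated correlation). Choline, betaine and methionine genes rose in 5 of 16 in 2i/LIF against serum/LIF (adjusted p = 0.00454, and adjusted p = 0.052 with an estimated correlation), but in 2 of 13 without the largest changes (adjusted p = 0.24).

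Among DNA methylation enzymes in 2i/LIF against serum/LIF, the cofactor gene Dnmt3l fell by 4.32 (adjusted p = 0.000635) and Uhrf1, which guides maintenance methylation, rose by 1.14 (adjusted p = 0.00227). That list, with 1 of 12 higher and 2 lower, did not pass camera in any comparison. Nor did BMP targets (2 of 12 higher, 4 lower in 2i/LIF against serum/LIF), definitive endoderm (1 and 2 of 11), mesoderm (1 and 2 of 16), fatty acid oxidation (3 and 1 of 19), glycolysis (1 and 2 of 21), the metal and selenium response (3 and 2 of 13) or cell cycle regulators (3 and 5 of 14). BMP targets did pass fry in 2i/LIF (adjusted p = 0.0050) and in KOSR/LIF (adjusted p = 0.020) against serum/LIF. For S phase genes limma called 0 higher and 1 lower of 19. For 37 oxidative phosphorylation genes limma called 0 in each comparison, with 1, 0 and 2 at an unadjusted p under 0.05, and for 20 G2/M genes it called 0, with 0, 0 and 2.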
